A study of Lactiplantibacillus plantarum with 36 samples.

How the data were processed

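Total RNA of Lactiplantibacillus plantarum, a lactic acid bacterium found in fermented plants, dairy products and animal guts, was sequenced in 36 libraries from 27 strains. Of these, 25 libraries came from strains grown on a medium that imitates the habitat they were isolated from, and 11 from strains grown in MRS broth, the usual laboratory medium for lactobacilli. The 9 habitat media were extracts of honey bee and Drosophila intestines, faecal extracts of omnivore and vegan volunteers, olive extract, tomato juice, pineapple juice, wheat flour hydrolysate and cheese broth. Each had 3 libraries except cheese broth, with 1. Media and strains are from the titles, which part omnivore from vegan only by strain name (FEO, FEV). Replicates follow sample order. Each library of a medium has its own strain name, none labelled a repeat culture, so p-values measure the spread between isolates.

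The authors deposited 1 table of RPKM values (reads scaled to gene length and to mapped reads, scaled per library by the authors) for 3108 genes, of which 3056 carry chromosomal locus tags of strain WCFS1 and 52 are named by plasmid proteins. Per the submitters' processing notes, TopHat was among the tools used, and the human build hg19 is named beside it. The genes carry WCFS1 names, so hg19 is not the genome behind these values. The genome actually used, the read counter, the strandedness of the libraries, the treatment of reads that match several genes, and all filters are not given in the sources used here. Values of overlapping genes and near-identical paralogs are therefore uncertain. A gene that is absent from a strain, or too diverged from WCFS1 for its reads to align, is listed at 0 just as an untranscribed gene is. The table gives 1358 genes a symbol. RefSeq's gene table of another strain (assembly ASM991365v1) served only for gene lengths, matched by symbol, so no coordinates are printed.

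The table holds no read counts. Because RPKM values of low genes are whole multiples of what 1 read is worth, the depth of each library was estimated from the spacing of its low values, over 352 genes with a length matched by symbol. Among values worth fewer than 20 reads, which 33 libraries hold, the share within 0.1 of a whole read had a median of 100% over libraries and was lowest at 66.7%. To see what the search finds by chance, the values of each library were jittered at random 39 times. This check was enlarged after a first one with 5 jittered libraries proved to depend on the random draw. In 35 of 36 libraries the score of the best-fitting depth lay above those of all its jittered copies, and in wheat replicate 2, with 4 against 4.05, it did not. Olive replicate 3, with 4.32, lay above its own copies but below the highest jittered score of any library, 4.51. At shallow, middle and deep simulated depths, 3 of 3 libraries each came back within 1 percent. These depths are estimates. They decided which libraries to leave out in an alternative, which to compare for gene content and which strains had like depth in both media in a test of the closing section. They also set the floor of a library, the RPKM of 3 reads on a gene of 1 kb, which covers counting error only. Floors decide which lowest changes are left out in the closing section and enter 1 of its tests of depth.

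Tests were run on log2(RPKM + 1), so fold changes are on that scale and understate the change of low genes. Genes with a mean of at least 1 RPKM over the libraries of a fit were kept. The tool was limma 3.58.1 in R 4.3.3, with an intensity trend in the moderated variance, and all adjusted p-values are Benjamini-Hochberg adjusted p-values from limma, called at 0.05. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for depths and plots. For 9 strains, 1 library in the own medium and 1 in MRS exist, and these 18 libraries were compared with strain as a block. Each of the 8 media with 3 libraries was compared with the 11 MRS libraries in 1 fit over all 36 libraries, so that all groups share 1 estimate of the spread. An F-test compared the 8 media with each other over 24 libraries. In the same fit, the 4 intestinal and faecal media were compared with the 4 plant media, and omnivore with vegan faecal extract. Correlations within and between media were compared by permuting the medium names.

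Before the data were examined, 33 lists of genes were fixed by their symbols, and 31 with at least 3 measured members were tested with limma's camera: glycolysis, pyruvate metabolism and fermentation, phosphotransferase system (PTS) sugar transport, pentose phosphate and pentose use, lactose, galactose and raffinose, beta-glucosidases, sucrose, maltose, trehalose and polyols, malate and citrate, phenolic acids and tannins, peptide uptake and peptidases, arginine synthesis, pyrimidine synthesis, purine synthesis, aromatic amino acids and histidine synthesis, sulfur, threonine and lysine amino acid synthesis, fatty acid synthesis, ribosomal proteins, aminoacyl-tRNA synthetases, ATP synthase, heat shock and Clp proteins, oxidative stress and redox, exopolysaccharide and capsule, teichoic acid, plantaricins, glycerol use, osmoprotectant uptake, riboflavin, folate and thiamine, cold shock, glycogen, metal transport, and competence. Bile salt hydrolases and ribosomal RNA had 1 member each and were not tested. Patterns on product names, fixed for some lists, found no use because the table holds none. Camera was run with a preset correlation of 0.01 between genes and again with an estimated correlation, adjusted over the lists of a comparison. Members were also counted with their p-values adjusted over the list alone.

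Genes named in the text follow a rule fixed before the data were examined and limited to genes with a symbol. For the 9 strains it takes up to 12 called genes each way with a mean of at least 10 RPKM and the same direction in at least 8 strains. For each medium it takes 3 each way that lie beyond every MRS library, or beyond the MRS median where fewer exist. It takes the 16 smallest F-test p-values among the 8 media, 10 each way between the intestinal and plant media, and up to 5 each way between the faecal media. In cheese broth it takes the 4 highest and 4 lowest ratios among genes of at least 50 RPKM in the higher library, and for a list up to 4 members with the smallest p.

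Strain names were checked by the genes listed at 0. The Jaccard similarity of these genes between the 2 libraries of a strain ran from 0.323 to 0.962. Deviations from the group means correlated between the 2 libraries of a strain at 0.192 to 0.794, across genes, and for 8 of 9 strains this was the best match. In 1 library, 15 genes above 30 RPKM were under 0.3 RPKM in the MRS library of the same strain name. By the rule for lineages given next, the 2 libraries were in 1 lineage for 8 of the 9 strains and not for 1, whose pair was kept. Among the 24 pairs of libraries of a medium, 0 were identical and the lowest chi-square per degree of freedom was 22, so none was counted as a repeat deposit. Libraries were joined into a lineage where no more than 2 genes were at 30 RPKM or more in one and under 0.3 in the other, in both directions. Libraries under 1000000 estimated reads were joined only to a deeper library of the same strain name, so lineages in Drosophila extract and the faecal extracts may be fewer than counted. By this measure the 3 bee libraries were 1 lineage, and 2 lineages each made up Drosophila extract, vegan faecal extract, tomato juice, pineapple juice and wheat flour hydrolysate.

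The fits were tested on simulated data with 200 changed genes. At a log2 change of 2, the comparison of 9 strains recovered 72% of the changed genes among 2951, the 8 comparisons with MRS 39% to 53% among 3082, the F-test 15% and the comparison of intestinal with plant media 84% among 3039. The F-test figure is for genes changed in 1 medium only. Camera recovered 10 of 10 changed lists and called 0 others, among 50 simulated lists of genes made independent of each other, so this does not test how correlated genes behave.

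The alternatives were other pseudocounts (0.1 and 10), no filter or a mean of at least 10 RPKM, centring each library on its median, quantile normalization, no trend, only genes above 0 in each group, other blocks and other libraries in the fit, and each library or strain left out in turn. All were chosen before the data were examined, except for 5 that were added after seeing the data: lineage as a random block, libraries of 1 lineage and medium averaged, leaving out the 4 libraries under 1000000 estimated reads, MRS libraries restricted to the 9 deep ones or to the other 2, and each MRS library left out in turn.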

Results

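Transcript levels of L. plantarum were compared between media that imitate 9 habitats and MRS broth, and among the habitat media, to ask how far the bacterium's transcription depends on where it grows. Values are means of deposited RPKM ± SD unless an SE is named. Changes are log2 fold changes with their SE from limma, and adjusted p-values are limma's. Where changes are given relative to the median of all genes, that median was subtracted from the fitted change, and the adjusted p is still that of the change as deposited. Of the 27 strains, 9 were measured in their own medium and in MRS, and the habitat isolates measured once cannot have strain and medium separated. Among the 48 pairs of a medium and a gene named against MRS there, the strain measured in both differed by less than 2-fold in 3: rfbB and rfbD in bee extract and pts24BCA in vegan faecal extract. For 1 of the 9 strains, gene content did not join the 2 libraries into 1 lineage. Isolates of a lineage, as the 3 bee libraries are, are not independent, which makes p-values too small. Averaging the libraries of 1 lineage in a medium was an alternative chosen after seeing the data.

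In MRS broth the most abundant transcript was that of tuf, which encodes elongation factor Tu, at 46380 ± 11585 RPKM (n = 11). The small heat shock gene hsp1 led in bee extract with 77548 ± 23370 RPKM, in omnivore faecal extract with 75855 ± 23765, in vegan faecal extract with 62141 ± 33105 and in tomato juice with 28245 ± 3728 (n = 3 each). In Drosophila extract a gene without a symbol, lp_2987, took 13.6% of the summed RPKM at 215937 ± 118083, and in olive extract it reached 105713 ± 108702 (n = 3 each).

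Depth, estimated from the spacing of low values in 34 libraries, ran from 125665 reads in Drosophila replicate 3 to 28756612 in MRS replicate 5, a 229-fold range. For wheat replicate 2 and olive replicate 3 no reliable estimate was had. Besides Drosophila replicate 3, 3 libraries had fewer than 1000000 estimated reads: Drosophila replicate 1 with 267047, omnivore replicate 1 with 572735 and vegan replicate 1 with 465924. The floors of these 4, in that order, were 23.87, 11.23, 5.24 and 6.44 RPKM. The 9 MRS libraries of habitat strains had 16804853 to 28756612 estimated reads, whereas the MRS libraries of WCFS1 and LB16 had 1929513 and 3286646. Between 28 genes (WCFS1) and 964 genes (Drosophila replicate 1) were listed at 0, which covers absent, diverged, silent and undersampled genes alike.

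Grouping by medium was tested by Pearson correlations of log2 values across 3039 genes. Bee libraries correlated at a mean of 0.996, tomato at 0.896, pineapple at 0.873, wheat at 0.868, olive at 0.856, Drosophila at 0.8, omnivore at 0.786 and vegan at 0.779, within which pairs ran from 0.665 to 0.991. The 24 pairs within a medium averaged 0.857 against 0.757 for the 252 between media, a difference of 0.099 (one-sided permutation p = 1e-05, the smallest 100000 permutations give). The most similar library came from the same medium for 19 of 24. Pairs of 1 lineage and medium, at 0.898 to 0.998, raise 0.857 and the 19. The permutation ignores lineage, so p does not test medium alone. Genes are not independent.

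**Figure D1:**
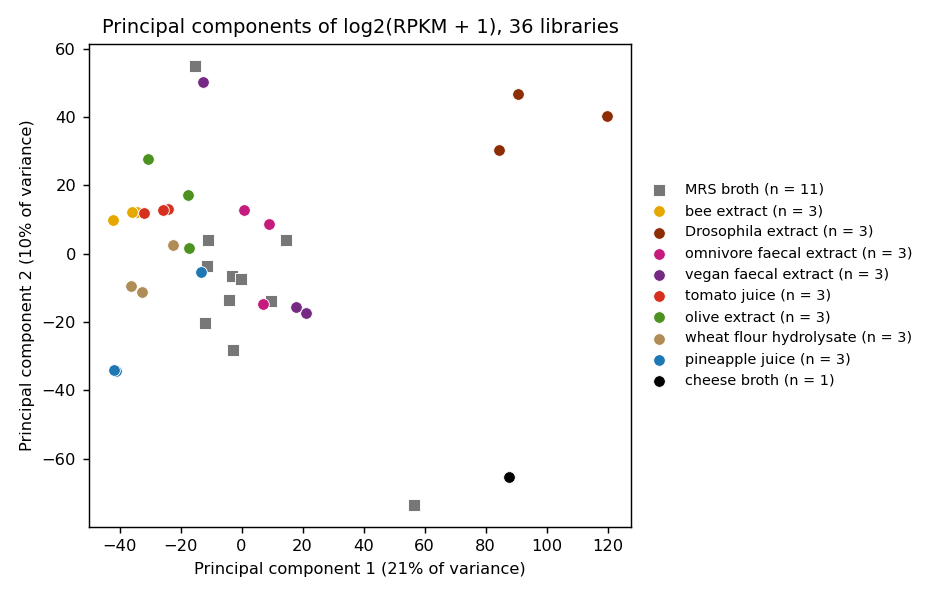
First and second principal components (percent of variance on each axis, 21% and 10%) of log2(RPKM + 1) over 3082 genes, 1 point for each of 36 libraries, coloured by medium.

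Which genes change when a strain moves from MRS to its own habitat medium was asked in 9 strains measured in both. The gene copA (lp_3055), for a copper-transporting ATPase, rose by 4.75 ± 0.84 (SE, adjusted p = 0.019), from 4 ± 2.41 to 1135 ± 2880 RPKM. Likewise mntH3 (lp_2992), for an Nramp-family manganese transporter, rose by 4.45 ± 0.77 (adjusted p = 0.019), from 16.7 ± 14.2 to 1026 ± 1385 RPKM (n = 9, both higher in 9 of 9 strains). Of the manganese ABC transporter genes, mtsC (lp_1095) rose by 4.45 ± 0.67 (adjusted p = 0.01) in 9 of 9 strains and mtsA (lp_1097) by 3.71 ± 0.73 (adjusted p = 0.025) in 8 of 9. The second copper ATPase gene copB (lp_3363) rose by 3.21 ± 0.70 (adjusted p = 0.035), and lrgA (lp_3254) by 3.95 ± 0.65 (adjusted p = 0.016). The metal transport list, lacking mtsC and mtsA, did not pass as a set (adjusted p = 0.2, 0.8 with an estimated correlation). Of 19 genes, copA, mntH3 and copB were higher and 0 lower, with 3 and 1 adjusted over the list alone or centred. The phosphate-binding protein gene pstF (lp_0733) rose by 2.82 ± 0.56, and fruK, for 1-phosphofructokinase, and fruA, for a fructose phosphotransferase component, by 2.31 ± 0.45 and 1.88 ± 0.37 (adjusted p = 0.025 each). Also higher were xylR (2.47 ± 0.48, adjusted p = 0.025) and pva2 (2.42 ± 0.53, adjusted p = 0.034).

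In the same 9 strains, the trehalose locus fell: pts4ABC (lp_0264) changed by -2.88 ± 0.44 (SE, adjusted p = 0.01), from 4013 ± 4630 in MRS to 641 ± 907 RPKM. In the same locus pts5ABC (lp_0265) was at -2.62 ± 0.48 (adjusted p = 0.02), treA (lp_0263) at -2.49 ± 0.42 (adjusted p = 0.018) and treR (lp_0262) at -2.06 ± 0.46 (adjusted p = 0.036). Among the genes named here, the largest fall was that of the purine synthesis gene purD (lp_2719), -3.38 ± 0.79 (adjusted p = 0.045), in 8 of 9 strains. The pyrimidine synthesis gene pyrE changed by -2.21 ± 0.48 (adjusted p = 0.034), and pck, for phosphoenolpyruvate carboxykinase, by -2.03 ± 0.42 (adjusted p = 0.027). The phosphotransferase components pts35B and pts35A changed by -2.62 ± 0.53 and -2.49 ± 0.56 (adjusted p = 0.025 and 0.039). Ribosomal protein genes changed by -1.98 ± 0.36 for rpmF (from 6441 ± 1354 to 1793 ± 801 RPKM), by -1.86 ± 0.35 for rplE (adjusted p = 0.02 each) and by -1.89 ± 0.38 for rpsE (adjusted p = 0.025).

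Counted over 2951 genes, 28 were higher and 35 lower in the own medium, 80 and 106 after centring each library on its median (limma, block on strain, n = 9). At an unadjusted p under 0.05 there were 519. Leaving out 1 strain changed the count of 63 to 147 without DE12, 39 without FEV11, 34 without WFH19, 25 without FEO3, 23 without OE1 and 22 without TJ22. Of the 23 genes named, copA, mntH3, mtsC, lrgA, pts4ABC, pts5ABC, treA and rpmF stayed called whichever strain was left out. The other 15 lost the call in at least 1 case: 14 each without OE1 and without TJ22, 13 without FEO3, 11 without WFH19, 10 without FEV11, 7 without CB5, 6 without BEE1ST, 5 without PJ16 and 1 without DE12. Their changes then ranged from 2.70 to 3.72 for copB, 3.34 to 4.24 for mtsA, 2.46 to 3.13 for pstF, 2.13 to 2.64 for fruK, 1.70 to 2.10 for fruA, 2.25 to 2.76 for xylR and 1.95 to 2.67 for pva2. Among the lower genes they ranged from -3.98 to -3 for purD, -2.84 to -2.20 for pts35B, -2.76 to -2.04 for pts35A, and -2.49 to -1.90 for pyrE. They were -2.37 to -1.74 for treR, -2.24 to -1.65 for pck, -2.06 to -1.69 for rplE and -2.13 to -1.62 for rpsE.

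The pair of libraries that gene content did not join was kept in this comparison. How MRS itself varied limits it too. The MRS libraries of WCFS1 and LB16, which were not part of the test, both lay on the MRS side of the midpoint for mntH3, mtsC, mtsA, copB, pva2, purD, pts35B, pts35A and pyrE, 9 of the 23 named genes. For copA, fruA, rpsE and rplE 1 of them did, and for 10 genes neither did: pts4ABC was at 223 and 340 RPKM there, lrgA at 848 and 101, and rpmF at 1146 and 1120. Fitted without the strain block, purD, pts35A, pts35B, fruK, fruA, pts4ABC, treA, pyrE, treR and pck lost their calls.

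Among the gene lists in the 9 strains, ribosomal proteins were lower as a set: 13 of 54 genes were lower and 0 higher, 37 and 0 adjusted over the list alone, and 12 and 0 after centring. Their median lay at -1.10 from that of all genes (adjusted p = 3.3e-19, camera with a preset correlation; adjusted p = 0.8 with an estimated correlation). Purine synthesis genes had a median of -2.61 (adjusted p = 4.7e-08; adjusted p = 0.8 with an estimated correlation), with 1 of 18 lower, 13 adjusted over the list alone and 10 centred, among them purH (-3.09 ± 0.77, SE) and purM (-3.48 ± 0.87). Pyrimidine synthesis had a median of -1.61 (adjusted p = 4.7e-05; 0.8 with an estimated correlation), with 1 of 14 lower, 9 adjusted over the list alone and 7 centred. Fatty acid synthesis had a median of -2 over 21 genes (adjusted p = 0.00082) and teichoic acid genes -0.46 over 23 (adjusted p = 0.0093; each 0.8 with an estimated correlation), with 0 genes called in either, over all genes or adjusted over the list alone, and 0 and 3 lower after centring. Fatty acid synthesis gene fabF, at -2.37 ± 0.91, had an adjusted p of 0.2 and dltD, at -1.78 ± 0.50, one of 0.086. Aromatic amino acid and histidine synthesis (median 0.39, 27 genes, adjusted p = 0.0093) and plantaricins (0.46, 23 genes, adjusted p = 0.015; each 0.8 with an estimated correlation) were higher as sets, with 0 genes called either way, centred or not. Phenolic acids and tannins (adjusted p = 0.9), exopolysaccharide and capsule (0.083), cold shock (0.36) and competence (0.64) passed neither here nor in any other comparison.

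**Figure D2:**
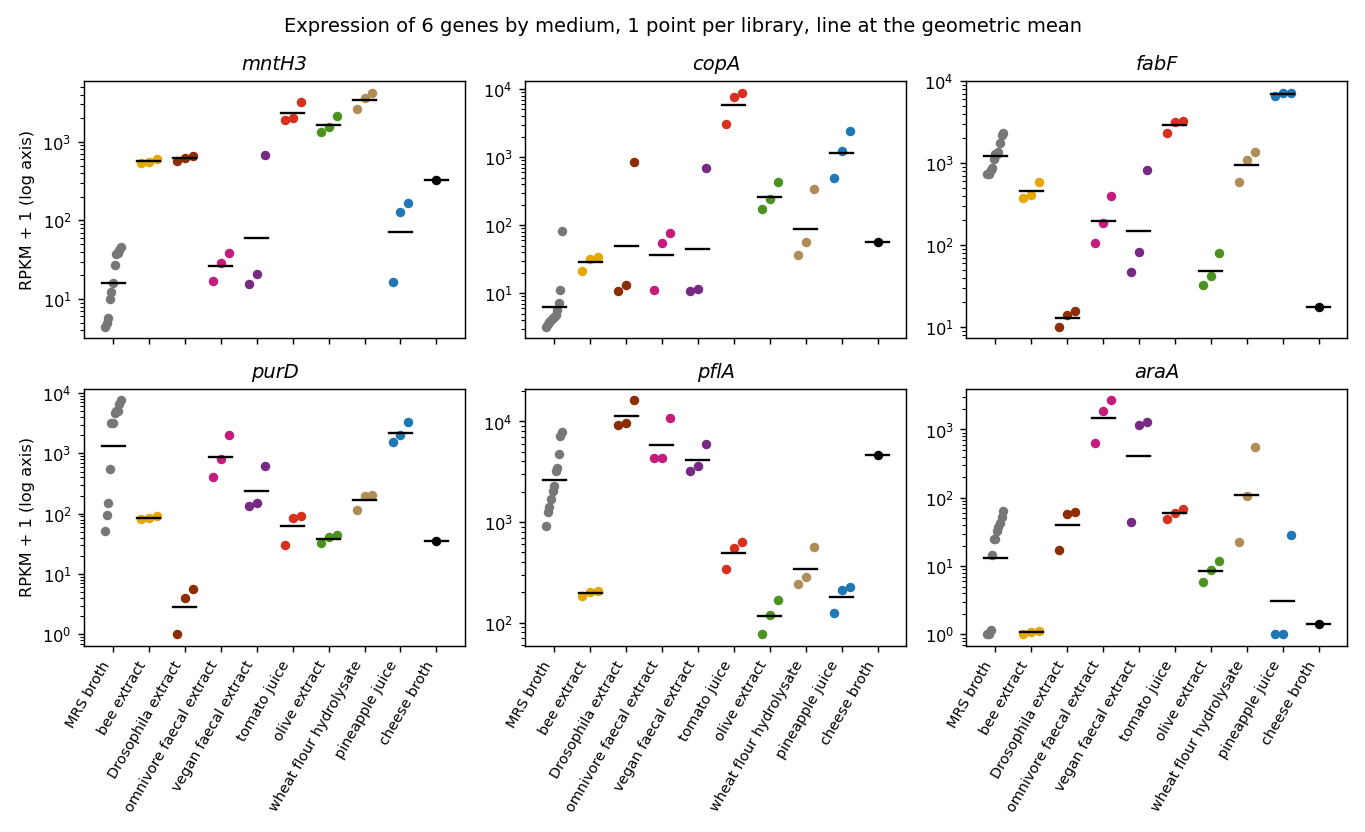
RPKM + 1 on a log axis for mntH3, copA, fabF, purD, pflA and araA, with 1 point per library in each of the 10 media and a line at the geometric mean. Mean copA levels were 6515 RPKM in tomato juice and 11.1 in MRS.

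In bee extract, compared with MRS to ask what intestinal extract of honey bees changes, glpD (lp_0371), for glycerol-3-phosphate dehydrogenase, was lower, with a change of -5.68 ± 1.07 (SE, adjusted p = 0.0016), at 10.3 ± 2.19 against 774 ± 760 RPKM (n = 3 and 11). All changes here are relative to the median of all genes, which lay at 0.51. The pyruvate dehydrogenase gene pdhB (lp_2153) was lower, with a change of -4.60 ± 0.55 (adjusted p = 1.4e-05) at 86 ± 9.8 against 2025 ± 2006 RPKM, and glpF3, for a glycerol facilitator, at -4.57 ± 1.09 (adjusted p = 0.011). The rhamnose precursor genes rfbB, rfbC and rfbD were higher by 5.50 ± 2.09, 5.23 ± 2.03 and 4.67 ± 1.66 (6.01, 5.74 and 5.18 as deposited, for which adjusted p = 0.045, 0.048 and 0.03), and listed at 0 in at least 1 MRS library. In strain BEE1ST itself they were at 509, 317 and 183 RPKM in bee extract against 308, 145 and 95.9 in MRS, log2 differences of 0.72, 1.13 and 0.92. After centring they missed the threshold (adjusted p = 0.08, 0.096 and 0.058). The 6 were chosen for every bee library lying beyond every MRS library.

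The same bee libraries had 425 genes higher and 99 lower of 3082, and 146 and 232 after centring. As lists, pyruvate metabolism and fermentation was lower (8 of 25 lower and 2 higher, the same adjusted over the list alone, 9 and 0 centred, adjusted p = 3.5e-07). It was led by pflB and pflA, for pyruvate formate-lyase and its activator, at -4.50 ± 0.51 and -4.22 ± 0.48. PTS sugar transport (5 of 63 lower and 1 higher, 1 and 0 adjusted over the list alone, 13 and 0 centred, adjusted p = 3.5e-07) and beta-glucosidases (4 of 15 lower and 0 higher, 4 and 1 adjusted over the list alone, 5 and 0 centred, adjusted p = 0.0051) were also lower. These 3 calls, from 3 libraries of 1 lineage, held with an estimated correlation (adjusted p = 0.03, 0.025 and 0.025). The next 4 did not (adjusted p = 0.33, 0.48, 0.4 and 0.53). No list was tested on lineage means. The 4 lost were pyrimidine synthesis (6 of 14 lower, 6 adjusted over the list alone, 7 centred) and purine synthesis (6 of 18 lower and 2 higher, 9 and 3 adjusted over the list alone, 9 and 0 centred). The others were lactose, galactose and raffinose (3 of 17, 3 adjusted over the list alone, 4 centred) and malate and citrate (2 of 11, 2 adjusted over the list alone). Fatty acid synthesis had 1 of 21 higher, 1 adjusted over the list alone and 6 lower after centring. Ribosomal proteins had 5 of 54 higher and 2 lower, 4 and 1 adjusted over the list alone but 1 and 16 after centring, and osmoprotectant uptake 0 of 6 called either way (adjusted p = 0.4, 0.82 and 0.58 with an estimated correlation).

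Single bee libraries mattered for 4 of the 6 named genes. The 524 calls became 204, 190 and 213 without bee replicate 1, 2 or 3. As deposited, rfbB (6.05, 5.94 and 6.05), rfbC (5.81, 5.65 and 5.78), rfbD (5.16, 5.16 and 5.22) and glpF3 (-3.99, -4.14 and -4.03) lost their calls without each in turn. Without MRS replicate 3, 4, 5, 6, 7, 8 or 10, rfbB was at 5.71 to 5.73 and rfbC at 5.47 to 5.51, not called. With lineage as a random block, rfbB, rfbC and rfbD were at 1.77, 2.16 and 1.66, not called, and against the MRS libraries of WCFS1 and LB16 alone rfbB (0.8), rfbC (1.25), rfbD (1.46), glpD (-2.69) and glpF3 (-1.16) were not either. With the 3 bee libraries averaged as 1 lineage, limma called 0 genes (289 at an unadjusted p under 0.05, smallest adjusted p = 0.064), so none of the 6 named: glpD was at -5.17, pdhB at -4.09, glpF3 at -4.06, rfbB at 6.01, rfbC at 5.74 and rfbD at 5.18. A single mean is there assumed to vary as the other groups do.

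Drosophila extract held the most genes lower than MRS, 1360 of 3082 against 175 higher, but 516 and 511 after centring. The median of all genes was -1.22, and changes are relative to it. The aldehyde-alcohol dehydrogenase gene adhE (lp_3662) was higher by 7.21 ± 1.13 (SE, adjusted p = 5.3e-05), at 7970 ± 1989 against 517 ± 1138 RPKM. Higher too were adc, for acetoacetate decarboxylase, by 6.56 ± 0.54 (adjusted p = 3.7e-09) and mntH3 by 6.49 ± 0.80 (adjusted p = 2.8e-06, n = 3 and 11). The GMP reductase gene guaC (lp_3271) was listed at 0, 3.09 and 0 RPKM in replicates 1 to 3 against 1346 ± 1119 in MRS (adjusted p = 1.2e-13). The purine synthesis gene purM was at 0, 2.21 and 0 against 1978 ± 1739 (adjusted p = 4.9e-08), and the fatty acid synthesis gene fabZ1 at 0, 14.5 and 0 against 1537 ± 1029 (adjusted p = 2e-12). The values of 0 come from the 2 libraries whose floors are 11.23 and 23.87 RPKM. No named call here was lost without any 1 library, and the count stayed between 1185 and 1675.

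As lists in Drosophila extract, fatty acid synthesis was lower (20 of 21 lower, 20 adjusted over the list alone, 15 centred, adjusted p = 1.1e-08; adjusted p = 0.14 with an estimated correlation), with fabF at -5.34 ± 0.51, under the floor in 2 of 3 libraries. Purine synthesis had 18 of 18 lower (18 adjusted over the list alone, 15 centred, adjusted p = 8.9e-08; 0.28 with an estimated correlation). Pyrimidine synthesis had 13 of 14 (13 adjusted over the list alone, 12 centred, adjusted p = 4.4e-05; 0.28 with an estimated correlation). Osmoprotectant uptake, with opuB at -3.51 ± 0.44, had 6 of 6 lower (6 adjusted over the list alone, 6 centred, adjusted p = 0.00045; 0.28 with an estimated correlation). Histidine and aromatic amino acid synthesis was higher relative to all genes (5 of 27 higher and 5 lower, the same adjusted over the list alone, 12 and 0 centred, adjusted p = 0.00045; 0.38 with an estimated correlation). Here hisG was at 4.59 ± 0.56 and hisE at 3.87 ± 0.41. Pyruvate metabolism was too (7 of 25 higher and 6 lower, the same adjusted over the list alone, 12 and 0 centred, adjusted p = 5e-05; 0.14 with an estimated correlation), with pdhB at 3.73 ± 0.55. Sucrose, maltose, trehalose and polyols had 7 of 24 higher and 7 lower, the same adjusted over the list alone and 12 and 4 centred (adjusted p = 0.011; 0.38 with an estimated correlation). Members mapA and treA were at 5.97 ± 0.81 and -3.76 ± 0.83. Relative to all genes, glycolysis, PTS sugar transport, pentose use and beta-glucosidases were higher as sets, but not with an estimated correlation (adjusted p = 0.5, 0.41, 0.28 and 0.14). As deposited, glycolysis had 1 of 9 higher and 1 lower (the same adjusted over the list alone, 6 and 0 centred) and PTS sugar transport 6 of 63 higher and 14 lower (5 and 12 adjusted over the list alone, 9 and 3 centred). Pentose use had 2 of 23 higher and 4 lower (2 and 3 adjusted over the list alone, 8 and 2 centred) and beta-glucosidases 1 of 15 higher and 2 lower (the same adjusted over the list alone, 5 and 1 centred). Lower as sets, though not with an estimated correlation (adjusted p = 0.41, 0.76 and 0.41), were peptide uptake, with 16 of 26 lower and 0 higher (18 and 1 adjusted over the list alone, 8 and 3 centred), ribosomal proteins, with 33 of 54 and 0 (the same adjusted over the list alone, 9 and 6 centred), and riboflavin, folate and thiamine, with 14 of 18 and 0 (17 and 0 adjusted over the list alone, 8 and 0 centred).

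In omnivore faecal extract the arabinose genes were higher than in MRS: araA (lp_3554) by 6.81 ± 1.23 (SE, adjusted p = 0.001), at 1725 ± 1025 against 26.1 ± 21.6 RPKM. Next were araD by 5.78 ± 1.2 (adjusted p = 0.0031) and araB by 5.07 ± 1.23 (adjusted p = 0.008, n = 3 and 11). Fatty acid synthesis genes were lower, fabG1 (lp_1674) at -2.85 ± 0.59 (adjusted p = 0.0031), at 216 ± 147 against 1457 ± 715 RPKM, fabZ1 at -2.79 ± 0.62 (adjusted p = 0.005) and fabD at -2.75 ± 0.62 (adjusted p = 0.0057). In total 138 genes were higher and 148 lower of 3082, and 120 and 147 after centring. The count of 286 became 176 without omnivore replicate 2 and 104 without omnivore replicate 3. Without the latter, fabG1 (-2.33), fabZ1 (-2.51), fabD (-2.23) and araB (5.08) were not called, and araB (4.66) was not without omnivore replicate 2. Against the MRS libraries of WCFS1 and LB16 alone, araB (5.66), fabD (-3.44), fabG1 (-3.45) and fabZ1 (-2.60) were not called.

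Among the lists in omnivore faecal extract, ribosomal proteins were lower (32 of 54, 45 adjusted over the list alone, 20 centred, adjusted p = 2.8e-22; adjusted p = 0.16 with an estimated correlation). So was fatty acid synthesis (11 of 21, 13 adjusted over the list alone, 11 centred, adjusted p = 3.2e-08; 0.16 with an estimated correlation). Heat shock and Clp proteins were higher (7 of 22, 7 adjusted over the list alone, 7 centred, adjusted p = 0.00082; 0.51 with an estimated correlation), with the chaperone gene dnaK at 1.70 ± 0.36 (SE) and clpE at 1.86 ± 0.34. Malate and citrate genes were higher too (2 of 11, 6 adjusted over the list alone beside 1 lower, adjusted p = 0.011; 0.59 with an estimated correlation), with the malolactic enzyme gene mleS at 5.49 ± 1.43. Beta-glucosidases (3 of 15 higher, 5 adjusted over the list alone, adjusted p = 0.16 with an estimated correlation) and plantaricins (0 of 23 called either way, adjusted p = 0.6 with an estimated correlation) were higher. Pyrimidine synthesis (2 of 14 lower, 9 adjusted over the list alone, 1 centred, adjusted p = 0.49 with an estimated correlation), aminoacyl-tRNA synthetases (1 of 23 lower and 1 higher, 5 and 1 adjusted over the list alone, 2 and 0 centred) and teichoic acid genes (4 of 28 lower, 5 adjusted over the list alone, 5 centred, each adjusted p = 0.59 with an estimated correlation) were lower.

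In vegan faecal extract pts26BCA (lp_3219), a phosphotransferase gene, was higher than in MRS by 5.22 ± 0.93 (SE, adjusted p = 0.00043), at 1849 ± 1504 against 32.7 ± 15.5 RPKM. Higher too were pts24BCA by 4.80 ± 1.52 (adjusted p = 0.034) and mtsC by 4.19 ± 0.59 (adjusted p = 7.2e-05, n = 3 and 11). Under the strain name measured in both media, pts24BCA was at 58.7 RPKM in vegan faecal extract and 50.9 in MRS, a log2 difference of 0.2, and 8 of the 11 MRS libraries listed it at 0. Lower were fabG1 at -3.48 ± 0.59 (adjusted p = 0.00033), at 311 ± 460 RPKM, the pyrimidine synthesis gene pyrC at -3.22 ± 0.77 (adjusted p = 0.0051) and fabZ1 at -3.14 ± 0.62 (adjusted p = 0.0011). In total 169 genes were higher and 229 lower of 3082, and 172 and 206 after centring. The count of 398 became 619 without vegan replicate 1, 84 without vegan replicate 2 and 121 without vegan replicate 3. The call of pts24BCA was lost without each (4.82, 4.74 and 4.83), and that of pyrC without vegan replicate 2 (-2.53) or 3 (-3.04). With lineage as a random block, pts24BCA (2.55) and pyrC (-3.14) were not called, and against the MRS libraries of WCFS1 and LB16 alone mtsC (2.69), fabZ1 (-2.95), pts24BCA (3.21) and pyrC (-3.07) were not. With libraries of 1 lineage averaged, the count was 62, and pts26BCA (4.47), pts24BCA (4.79) and pyrC (-2.78) were not called. Vegan replicate 1 also held genes otherwise listed only in WCFS1.

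Arginine synthesis stood out among the lists in vegan faecal extract, with 9 of 12 genes higher and 1 lower, the same adjusted over the list alone and 9 and 0 centred. Its median was 3.92 (adjusted p = 0.00014; adjusted p = 0.43 with an estimated correlation). Of its genes, argJ and carB were higher by 4.47 ± 1.12 and 4.77 ± 1.26 (SE). Ribosomal proteins (32 of 54, 41 adjusted over the list alone, 26 centred, adjusted p = 2.9e-20) and pyrimidine synthesis (11 of 14, 12 adjusted over the list alone, adjusted p = 2.8e-08) were lower. So was fatty acid synthesis (12 of 21, 12 adjusted over the list alone beside 1 higher, adjusted p = 6.7e-08). Each of these 3 had an adjusted p = 0.21 with an estimated correlation. Also lower, but not with an estimated correlation (adjusted p = 0.43, 0.43 and 0.44), were purine synthesis (4 of 18, 14 adjusted over the list alone), aminoacyl-tRNA synthetases (8 of 23 and 1 higher, 14 and 1 adjusted over the list alone) and teichoic acid genes (7 of 28 and 1 higher, 8 and 1 adjusted over the list alone) with dltD at -2.87 ± 0.53. The same held for sulfur, threonine and lysine amino acid synthesis (3 of 27 and 1 higher, 9 and 1 adjusted over the list alone; adjusted p = 0.44 with an estimated correlation) and ATP synthase (2 of 8, 4 adjusted over the list alone, 0 centred; 0.49 with an estimated correlation). Glycolysis (4 of 9, 4 adjusted over the list alone, 2 centred; adjusted p = 0.44 with an estimated correlation) and peptide uptake (3 of 26, 3 adjusted over the list alone; 0.43 with an estimated correlation) were lower as well. Metal transport (3 of 22, 3 adjusted over the list alone), heat shock and Clp proteins (5 of 22, 7 adjusted over the list alone, 3 centred) with clpB at 1.90 ± 0.38, and plantaricins (0 of 23 called either way) were higher. With an estimated correlation these 3 were not called (adjusted p = 0.57, 0.61 and 0.61).

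Tomato juice had copA higher than MRS by 9.44 ± 1.09 (SE, adjusted p = 1.3e-07), at 6515 ± 3076 against 11.1 ± 23 RPKM. Higher were also copB by 7.01 ± 0.84 (adjusted p = 1.8e-07), at 6963 ± 2729 against 45.5 ± 30.7, and valT by 7.02 ± 0.97 (adjusted p = 2.4e-06, n = 3 and 11). Changes are relative to the median of all genes, 0.43. Pyruvate formate-lyase genes pflA (lp_3314) and pflB (lp_3313) were lower, with changes of -2.83 ± 0.48 and -2.82 ± 0.51 (adjusted p = 0.0014 and 0.0027), and the ferrous iron transport gene feoA (lp_1467) at -2.91 ± 0.63 (adjusted p = 0.012). Of 3082 genes, 233 were higher and 44 lower, but 71 and 70 after centring. The count of 277 became 84, 159 and 87 without tomato replicate 1, 2 or 3, and feoA, as deposited, was at -2.42 without tomato replicate 1 and -2.28 without replicate 3, not called. Against the MRS libraries of WCFS1 and LB16 alone pflA (-1.2), pflB (-0.98) and feoA (-2.21) were not called. With libraries of 1 lineage averaged, the count was 54, and as deposited feoA (-2.35) was not called.

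Aromatic amino acid and histidine synthesis was a higher list in tomato juice (7 of 27 higher, 16 adjusted over the list alone, 3 centred, adjusted p = 0.00017; adjusted p = 0.61 with an estimated correlation). It was led by aroC2 at 4.82 ± 0.46 (SE, adjusted p = 1.9e-09). Heat shock and Clp proteins (6 of 22 higher, 10 adjusted over the list alone, 0 centred, adjusted p = 0.00041; 0.61 with an estimated correlation) were higher as well. So was glycogen (2 of 5, 4 adjusted over the list alone, 0 centred, adjusted p = 0.037; 0.72 with an estimated correlation). Pyruvate metabolism was lower (8 of 25 lower and 1 higher, 8 and 5 adjusted over the list alone, 8 and 0 centred, adjusted p = 0.0013; 0.61 with an estimated correlation), with pdhD at -2.78 ± 0.44. Purine synthesis (2 of 18, 2 adjusted over the list alone, adjusted p = 1.3e-06; 0.61 with an estimated correlation) and ribosomal proteins (1 of 54, 0 adjusted over the list alone, adjusted p = 1.5e-07; 0.72 with an estimated correlation) were lower, with purD at -4.86 ± 1.11.

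In olive extract the alcohol dehydrogenase gene adh2 (lp_2873) was higher than in MRS by 7.68 ± 0.40 (SE, adjusted p = 8.7e-16), at 12267 ± 2611 against 42.5 ± 11.2 RPKM. Higher too were the enolase gene enoA2 (lp_1920) by 7.09 ± 0.71 (adjusted p = 5.4e-09) and the manganese-transporting ATPase gene mntA (lp_1919) by 6.49 ± 0.70 (adjusted p = 1.6e-08, n = 3 and 11). Changes are relative to the median of all genes, 0.48. Lower were purM at -5.69 ± 1.09 (adjusted p = 0.0012), purD at -5.58 ± 1.11 (adjusted p = 0.0017), at 38.1 ± 5.65 against 3292 ± 2748 RPKM, and fabG1 at -5.34 ± 0.59 (adjusted p = 5.2e-07), at 49.3 ± 29.5 RPKM. In strain OE1 itself purM was at 20.1 RPKM against 44.6 in MRS and purD at 31.8 against 95.8, log2 differences of -1.11 and -1.56. Of 3082 genes, 372 were higher and 157 lower, but 156 and 245 after centring. The count of 529 became 313, 302 and 248 without olive replicate 1, 2 or 3, and the 6 named genes stayed called.

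Of the lists in olive extract, purine synthesis (13 of 18 lower and 1 higher, 14 and 1 adjusted over the list alone, 14 and 0 centred, adjusted p = 5.2e-13; adjusted p = 0.14 with an estimated correlation) was lower, with purL at -5.33 ± 0.97 (SE). Fatty acid synthesis was lower too (12 of 21 lower and 1 higher, 12 and 3 adjusted over the list alone, 12 and 0 centred, adjusted p = 1.3e-10; 0.14 with an estimated correlation), with fabF at -5.15 ± 0.51. Ribosomal proteins were lower (26 of 54 lower and 3 higher, 30 and 5 adjusted over the list alone, 31 and 0 centred, adjusted p = 2.9e-15; 0.26 with an estimated correlation), with rplP at -2.66 ± 0.47. Pyrimidine synthesis was lower as well (6 of 14, 7 adjusted over the list alone, 8 centred, adjusted p = 0.26 with an estimated correlation). Pyruvate metabolism had pflA at -4.97 ± 0.48 and pdhD at -4.33 ± 0.44 (7 of 25 lower and 3 higher, 7 and 4 adjusted over the list alone, 8 and 1 centred, adjusted p = 0.52 with an estimated correlation).

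In wheat flour hydrolysate mntH3 was higher than in MRS by 7.23 ± 0.80 (SE, adjusted p = 3e-07), to 3464 ± 821 RPKM. Higher too were malT (lp_1729) by 4.95 ± 0.78 (adjusted p = 3.3e-05), at 583 ± 342 against 15.3 ± 16.5, and mtsC by 4.82 ± 0.59 (adjusted p = 7.8e-07, n = 3 and 11). Changes are relative to the median of all genes, 0.49. Lower were pflA at -3.43 ± 0.48 (adjusted p = 0.00028), glpD at -4.62 ± 1.07 (adjusted p = 0.017), though not below every MRS library, and rbfA, for a ribosome-binding factor, at -1.58 ± 0.31 (-1.09 as deposited, for which adjusted p = 0.027, and 0.0045 centred). Of 3082 genes, 249 were higher and 22 lower, but 28 and 66 after centring. The count of 271 became 46 without wheat replicate 2 and 75 without wheat replicate 3. As deposited, glpD was at -3.79 without wheat replicate 2 and -3.82 without replicate 3, and rbfA at -0.83, -1.24 and -1.2 without replicate 1, 2 or 3, not called. Against the MRS libraries of WCFS1 and LB16 alone pflA (-1.74), glpD (-1.64), rbfA (-0.49) and malT (4.40) were not called. With libraries of 1 lineage averaged, the count was 28, and as deposited glpD (-4.28) and rbfA (-1.04) were not called.

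Pyruvate metabolism was lower as a list in wheat flour hydrolysate (7 of 25 lower and 1 higher, 9 and 3 adjusted over the list alone, 9 and 0 centred, adjusted p = 2.7e-05; adjusted p = 0.23 with an estimated correlation). Here pflB was at -3.03 ± 0.51 (SE) and pdhD was at -2.57 ± 0.44. Pyrimidine synthesis (0 of 14 called, 6 lower adjusted over the list alone, 2 lower centred, adjusted p = 0.00034; 0.61 with an estimated correlation) was lower as a set. So were purine synthesis (1 of 18 higher, 1 adjusted over the list alone, 0 centred, adjusted p = 0.00049; 0.63 with an estimated correlation) and PTS sugar transport (0 of 63 called either way, adjusted p = 0.00084; 0.23 with an estimated correlation). The same held for ribosomal proteins (4 of 54 higher, 4 adjusted over the list alone, 1 lower centred, adjusted p = 0.018; 0.81 with an estimated correlation) and oxidative stress and redox genes (2 of 21 higher, 2 adjusted over the list alone, 1 lower centred, adjusted p = 0.034; 0.63 with an estimated correlation). For rpsB, at 1.01 ± 0.36, and trxB, at 1.11 ± 0.45, the single genes went the other way than their lists, whose medians lay below that of all genes.

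In pineapple juice copA was higher than in MRS by 7.13 ± 1.09 (SE, adjusted p = 3.5e-05), to 1381 ± 971 RPKM. Higher were also pstF by 5.04 ± 0.63 (adjusted p = 9.6e-07), at 582 ± 125 against 17.9 ± 19.7, and the biotin ligase gene birA1 (lp_0337) by 4.62 ± 0.41 (adjusted p = 7.2e-10), at 1021 ± 62.8 against 34.6 ± 18.4 (n = 3 and 11). Changes are relative to the median of all genes, 0.36. Lower were pflA at -4.21 ± 0.48 (adjusted p = 3.2e-06), pts4ABC at -3.56 ± 0.96 (adjusted p = 0.023) and the phosphoketolase gene xfp (lp_3551) at -3.38 ± 1.02 (adjusted p = 0.044). Of 3082 genes, 354 were higher and 102 lower, but 169 and 226 after centring. The count of 456 became 148 without pineapple replicate 2 and 145 without pineapple replicate 3. As deposited, pts4ABC was at -3.08 and -3.15 without these, not called, and xfp was not called without pineapple replicate 1 (-3.09), 2 (-3.01) or 3 (-2.95) or without MRS replicate 3, 6, 7, 8, 9 or 10 (-3.06 to -2.60). Against the MRS libraries of WCFS1 and LB16 alone copA (5.54), pts4ABC (-0.77) and xfp (-1.83) were not called. With libraries of 1 lineage averaged, the count was 119, and as deposited pts4ABC (-3.11) and xfp (-2.98) were not called.

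Fatty acid synthesis was higher in pineapple juice (14 of 21 higher, 14 adjusted over the list alone, 9 centred, adjusted p = 0.00022; adjusted p = 0.38 with an estimated correlation). The acyl carrier protein gene acpA2 was at 15443 ± 443 RPKM and 2.80 ± 0.62 (SE) and fabF at 2.15 ± 0.51. Aromatic amino acid and histidine synthesis was higher (10 of 27, 16 adjusted over the list alone, 5 centred, adjusted p = 0.00022; 0.38 with an estimated correlation), with trpF at 2.99 ± 0.63. Plantaricins were lower (1 of 23, 1 adjusted over the list alone, 3 centred, adjusted p = 0.00028; 0.42 with an estimated correlation), with plnD at -3.97 ± 0.93. So was pyruvate metabolism (7 of 25, 7 adjusted over the list alone, 8 centred, adjusted p = 0.00024; 0.38 with an estimated correlation). Pentose use (2 of 23 lower, 1 adjusted over the list alone, 4 centred; adjusted p = 0.38 with an estimated correlation) and osmoprotectant uptake (1 of 6, 1 adjusted over the list alone; 0.65 with an estimated correlation) were lower as sets. So were glycerol use (3 of 15 lower and 1 higher, the same adjusted over the list alone; adjusted p = 0.42 with an estimated correlation) and PTS sugar transport (2 of 63 lower and 3 higher, the same adjusted over the list alone, 6 and 3 centred; 0.38 with an estimated correlation).

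**Figure D3:**
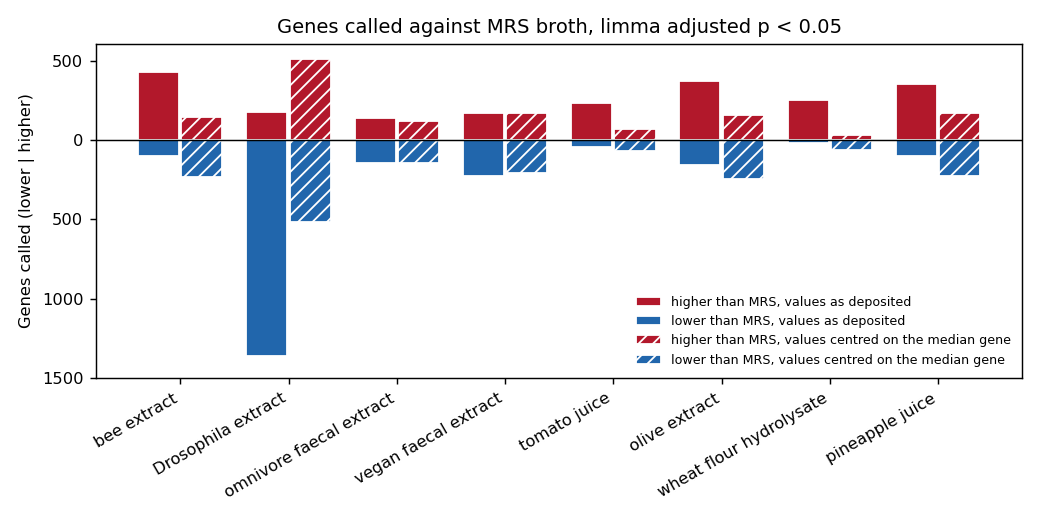
Number of genes higher and lower than in MRS (adjusted p under 0.05, 3082 genes) for 8 media, as deposited and after centring each library on its median. In Drosophila extract, 1360 lower and 175 higher became 516 and 511.

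**Figure D4:**
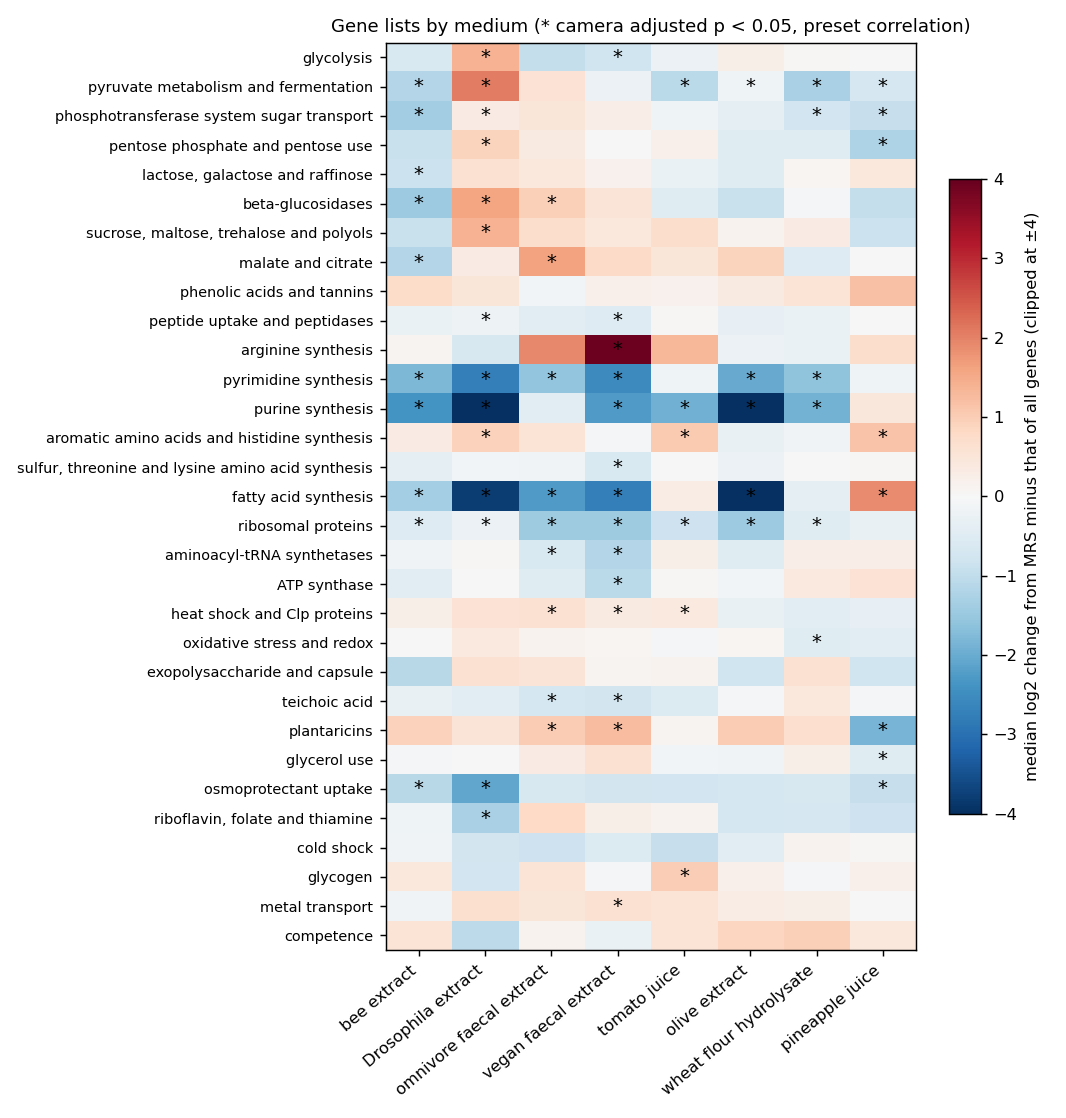
Median log2 change of each gene list minus that of all genes, for 8 media against MRS, as a colour scale. An asterisk marks an adjusted p under 0.05 by camera with the preset correlation, and only 3, all in bee extract (1 lineage), held with an estimated one.

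Which genes differ among the 8 replicated media was asked with limma's F-test, and pflA led (adjusted p = 2.1e-09), from 11694 ± 3905 RPKM in Drosophila extract to 121 ± 46.5 in olive extract (n = 3 each). The pyruvate dehydrogenase genes pdhB, pdhC and pdhD were also highest in Drosophila extract, at 8636 ± 2190, 5013 ± 332 and 4247 ± 1078 RPKM. They were lowest in bee extract for pdhB and pdhC, at 86 ± 9.8 and 69.3 ± 4.37, and in olive extract for pdhD, at 81 ± 20.4 (adjusted p = 1.2e-07, 5.1e-08 and 3.5e-08). Fatty acid synthesis genes were highest in pineapple juice, with fabH2 at 8292 ± 934 RPKM, fabF at 6970 ± 282, fabZ1 at 8445 ± 683, accC2 at 4835 ± 575 and fabI at 4523 ± 926. They were lowest in Drosophila extract, where fabF was at 12.2 ± 2.8 (adjusted p = 4.1e-08 to 1.1e-07). Purine synthesis genes purB and purA, like guaC, were highest in bee extract, at 1334 ± 108, 1351 ± 66.2 and 873 ± 114 RPKM, and purD and purK1 in pineapple juice, at 2288 ± 920 and 696 ± 137. All 5 were lowest in Drosophila extract (adjusted p = 6.7e-09 to 1.2e-07). The GTPase gene typA ran from 2109 ± 75.4 in bee extract to 92.2 ± 29.1 in Drosophila extract (adjusted p = 6.7e-09), and adh2 from 12267 ± 2611 in olive extract to 30.8 ± 6.85 in vegan faecal extract (adjusted p = 2.3e-08).

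In that F-test 2155 of 3039 genes (70.9%) differed among the media, 1981 of them with a range of at least 4-fold between media means. Drosophila extract held the lowest mean for 1499 of the genes called and pineapple juice the highest for 401, bee extract for 428. No named call was lost without any 1 library. Spread within a medium is that between libraries of different strain names, some of them of 1 lineage. With lineage as a random block the count was 855, and with libraries of 1 lineage averaged it was 946.

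The 4 intestinal and faecal and 4 plant media were compared over 12 and 12 libraries. The gene pflA was higher in the former by 4.15 ± 0.21 (SE, adjusted p = 1.5e-09), at 5664 ± 4944 against 295 ± 190 RPKM. Next came glpF3 with 4.05 ± 0.55 (adjusted p = 6.5e-05), at 2108 ± 3443 against 34.2 ± 25.5, and pdhD, pdhC and pdhB with 3.63 ± 0.24, 3.29 ± 0.26 and 2.97 ± 0.28 (adjusted p = 1.4e-07, 1e-06 and 3.6e-06). Bee extract did not share this, with means of 198 (pflA), 139 (pdhD), 69.3 (pdhC), 86 (pdhB) and 13 RPKM (glpF3). Nor did Drosophila replicates 1 and 2 for glpF3, at 72.5 and 43.9 (plant maximum 76.1). Changes are relative to the median of all genes, -0.66. Higher too were lamD, for an autoinducing peptide, by 4.14 ± 1.14 (adjusted p = 0.016), and the maltodextrin-binding protein gene mdxE by 3.38 ± 0.71 (adjusted p = 0.0039). So were pps, for phosphoenolpyruvate synthase, by 3.21 ± 0.51 (adjusted p = 0.00042), and plnN and plnO of the plantaricin locus by 3.77 ± 1.05 and 2.99 ± 0.69 (adjusted p = 0.02 and 0.009). The mdxE difference rested on Drosophila replicates 1 and 2, at 59345 and 51243 RPKM, and pineapple replicates 2 and 3, at 0.59 and 0. Bee (216 to 237) and vegan (480 to 1063) libraries lay below the 3 wheat libraries (1422 to 4661). Nor did bee extract share the pps difference (24.9 to 28.9 RPKM, plant libraries 27.2 to 1653). The lamD level rested on bee extract, at 2602, 3202 and 2589 RPKM, and vegan replicate 1, at 454, with the other 8 of the 12 at 0 to 29.2. Olive replicate 3 held 2328 RPKM, and in MRS strains BEE1ST and WCFS1 held 6073 and 5511. In 7 of the 12 plant libraries plnN was at 0 to 0.71 RPKM and plnO at 0. In olive replicates 1 and 3 and wheat replicate 1 plnN was at 95.4, 159 and 133 RPKM, above the 3 bee libraries, at 29.4 to 42.6, and Drosophila replicate 3, at 0. The highest plnN levels, 646, 294 and 218, were in 3 of the libraries under 1000000 estimated reads. With lineage as a random block lamD (3.54), plnN (3.08) and plnO (2.29) were not called, and with libraries of 1 lineage averaged, as deposited, lamD (3.7), plnN (2.98), plnO (2.28) and mdxE (2.27) were not.

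Lower in the intestinal and faecal media were copA at -3.36 ± 0.74 (SE, adjusted p = 2e-04), at 149 ± 287 against 2080 ± 3050 RPKM, pts2CB at -2.49 ± 0.39 (adjusted p = 5.3e-06), apbE3 at -2.51 ± 0.42 (adjusted p = 8.8e-06) and fatty acid synthesis genes. Of these, fabZ1 was at -3.22 ± 0.40 (adjusted p = 1.2e-06), accC2 at -2.76 ± 0.39, accB2 at -2.63 ± 0.48, fabH2 at -2.54 ± 0.35, acpA2 at -2.53 ± 0.40, fabZ2 at -2.51 ± 0.53 and fabG1 at -2.46 ± 0.41 (adjusted p = 1.7e-06 to 7.7e-05). Olive extract had low levels of these fatty acid genes too, with fabF at 50.5 RPKM. Drosophila replicate 3 and vegan replicate 1 held 834 and 682 RPKM of copA, above the 3 olive and 3 wheat libraries. Of 3039 genes, 177 were higher and 1278 lower, but 396 and 381 after centring, and no named call was lost without any 1 library. With libraries of 1 lineage averaged, the count was 727. The 1455 is not particular to this grouping: 4 of 35 into 4 and 4 called as many, itself included.

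Of the lists, beta-glucosidases were higher in the intestinal and faecal media (3 of 15, 1 adjusted over the list alone, 9 centred, adjusted p = 0.00067), with pbg6 at 1.98 ± 0.37 (SE), and this call held with an estimated correlation (adjusted p = 0.018). Bee extract did not share it: against MRS, relative to all genes, the median was -1.46 there, below those of tomato juice (-0.49), olive extract (-0.88), wheat flour hydrolysate (-0.08) and pineapple juice (-0.94). It was 1.59 in Drosophila, 0.96 in omnivore and 0.53 in vegan faecal extract. Pyruvate metabolism was higher (8 of 25 higher and 6 lower, the same adjusted over the list alone, 8 and 2 centred, adjusted p = 3.7e-05; adjusted p = 0.15 with an estimated correlation). Its medians against MRS were 2.04 in Drosophila and 0.58 in omnivore, but -0.25 in vegan and -1.17 in bee extract, beside -0.16 in olive, -0.67 in pineapple, -1.07 in tomato and -1.29 in wheat media. For 0 of the 14 lists called here did the medians of all 4 intestinal and faecal media lie beyond those of all 4 plant media. Fatty acid synthesis was lower (18 of 21, 18 adjusted over the list alone, 15 centred, adjusted p = 1.2e-05; 0.22 with an estimated correlation). Heat shock and Clp proteins were higher relative to all genes (8 of 22 higher and 8 lower, the same adjusted over the list alone, 12 and 2 centred, adjusted p = 0.0048; 0.37 with an estimated correlation). Here hsp1 was at 2.90 ± 0.27 and clpE at 2.27 ± 0.18. After centring, PTS sugar transport had 11 of 63 higher and 2 lower, pentose use 7 of 23 higher, glycerol use 6 of 15 higher and 1 lower and plantaricins 3 of 23 higher. These set calls were lost with an estimated correlation (adjusted p = 0.2, 0.2, 0.4 and 0.46). As deposited these had 6 and 9, 5 and 4, 4 and 4, and 2 and 3, and adjusted over the list alone 4 and 7, 5 and 4, 5 and 5, and 0 and 0. Lower as sets were pyrimidine synthesis (14 of 14, 14 adjusted over the list alone, 8 centred) and purine synthesis (16 of 18, 16 adjusted over the list alone, 2 centred; for each, adjusted p = 0.49 with an estimated correlation). So were aminoacyl-tRNA synthetases (18 of 23 beside 1 higher, 19 and 1 adjusted over the list alone, 6 and 1 centred; adjusted p = 0.62 with an estimated correlation) and ATP synthase (8 of 8, 8 adjusted over the list alone, 0 centred; 0.66 with an estimated correlation). Ribosomal proteins (31 of 54, 31 adjusted over the list alone, 4 centred beside 3 higher; adjusted p = 0.69 with an estimated correlation) and peptide uptake (17 of 26 beside 1 higher, 18 and 1 adjusted over the list alone, 8 and 4 centred; 0.46 with an estimated correlation) were lower as well.

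Omnivore and vegan faecal extract were compared to ask whether the donors' diet is reflected in the bacterium's transcription. No gene was called: limma found 0 of 3039 (n = 3 and 3, smallest adjusted p = 0.96), 105 had an unadjusted p under 0.05 where 152 are expected, and 8 were called without omnivore replicate 3. The arabinose genes araA, araB and araD and the arginine genes argJ and carB were thus not shown to differ between the faecal media. On simulated data this comparison recovered 38% of changes of a log2 of 2. Omnivore replicate 3 shares a lineage with vegan replicates 2 and 3.

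Strain CB5 was measured once in cheese broth and once in MRS, so its values carry no test. The manganese transport genes mtsC, mtsB and mtsA were at 268, 273 and 216 RPKM in cheese broth against 4.49, 11.7 and 13.4 in MRS, and the pyruvate oxidase gene pox5 at 1895 against 120. The riboflavin synthesis genes ribH and ribA were at 12.3 and 14.3 against 2620 and 2052 RPKM, and the fatty acid synthesis genes acpA2 and fabG1 at 6.84 and 6.16 against 1039 and 848. These are the 4 highest and 4 lowest ratios of 726 genes, and the median log2 ratio was -0.53. Against 10000 random lists of like expression, the medians of purine synthesis (-5.98), fatty acid synthesis (-4.91), pyrimidine synthesis (-2.91), ribosomal proteins (-2.24) and aminoacyl-tRNA synthetases (-2.06) lay at the lowest end, percentile 0. Those of aromatic amino acid and histidine synthesis (1.23) and of lactose, galactose and raffinose (0.80) lay at percentile 100.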

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

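The test on a few abundant genes in Drosophila extract and the tests on the 9 strains below were chosen after the results were seen.

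Of the genes named in the report, 20 were higher than MRS in at least 1 medium and lower in at least 1 other, with and without centring, and differed among the 8 media by limma's F-test. The values are F-test adjusted p-values, followed by the highest and lowest log2 change from MRS as deposited. The lowest is left out where a library of that medium was listed at 0 or at least 2 of its 3 lay under their floor. The pyruvate genes pflA (2.1e-09, 2.12 in Drosophila and -4.49 in olive extract), pdhB (1.2e-07, 2.52 in Drosophila and -4.09 in bee extract), pdhC (5.1e-08, 2.36 and -3.79 in the same media) and pdhD (3.5e-08, 1.84 in Drosophila and -3.85 in olive extract) were highest in Drosophila extract. So were xfp (0.00027, 2.94 against -3.24 in bee extract) and mdxE (7.9e-05, at 6.22, with 2 of 3 pineapple libraries under their floor). In strain BEE1ST itself xfp was at 42.9 RPKM in bee extract and 53.6 in MRS, while the MRS libraries of strains OE1 and CB5 held 6962 and 3801. Highest in omnivore faecal extract and lowest in bee extract were araA (1.2e-05, 6.81), araD (4.7e-06, 5.78), araB (3.7e-06, 5.07) and pps (9.5e-06, 4.02 and -3.84). In bee extract araA and araB were under the floor in 3 of 3 libraries and araD in 2, and in MRS strain BEE1ST held 0, 0.04 and 0.08 RPKM of araA, araB and araD. The gene glpF3 (1.3e-05) was highest in vegan faecal extract at 3.71 and lowest in bee extract at -4.06. Highest in pineapple juice and lowest in Drosophila extract were fabF (7.1e-08, 2.51, with 2 of 3 Drosophila libraries under their floor), fabG1 (6.4e-07, 2.86 and -5.73, with 1 of 3 under its floor), fabD (9.9e-07, 2.97 and -4.96), fabH2 (1.1e-07, 2.72 and -5.92), acpA2 (6.1e-07, 3.16 and -5.02), and fabZ1 (4.1e-08), fabZ2 (7.1e-06) and accC2 (8.1e-08). The last 3 are listed at 0 in Drosophila libraries, so only their highest changes are given, 2.69, 2.39 and 2.38. The gene typA (6.7e-09) was highest in bee extract at 1.75 and lowest in Drosophila extract at -2.81.

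Lower calls outnumber higher ones in Drosophila extract. With every library scaled to its sum without its 10 highest genes the median log2 difference was -1.09 rather than -1.22, which argues against a few abundant genes as the main cause. Among 1474 genes with a mean of at least 100 RPKM, lower calls were 6.3 times the higher ones, 735 against 116, which argues against shallow depth of replicates 1 and 3 as the whole cause. The replicate medians were -1.45, -1.22 and -0.90 against -0.53 to 0.28 in single MRS libraries. Another normalization step by the authors and a true shift in transcript composition both stay open, and since RPKM is relative, neither direction count shows how total RNA changed.

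The 9 MRS libraries of habitat strains are deeper than the 2 of WCFS1 and LB16 and may stem from a separate sequencing run, which the labels do not state. Of genes called in the 9 strains, WCFS1 lay on the MRS side of the midpoint for 38.1%, LB16 for 58.7% and both for 27%. Most did not recur in both, which goes with a run effect. Strain differences of these 2 would give the same pattern and stay open. Of the 63 genes called, 53 stayed called without the 4 shallow libraries and lay above the floor in every library of the 7 strains left, which argues against read depth as the whole cause. For genes chosen in 7 strains, 84% kept their direction in the 2 strains of like depth in both media, but 8 of 64 ways to swap the media within those 7 gave a share as far from 50%, so this decides nothing.

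Of 53 genes at 10 RPKM or more in WCFS1 and under 0.5 RPKM in every other library but vegan replicate 1, 40 were above 0 in vegan replicate 1. Over all 53, those at 0 included, its median was 8.7% of the WCFS1 value, and with any other library exempted in its place at most 5 such genes were found. Of 467 genes abundant in WCFS1, 0.2% lay under 50% of that share, against 12.4% to 26.1% in 24 other libraries, which goes with RNA or reads of WCFS1 in this library. Reads of the WCFS1 library and RNA of another WCFS1 culture both stay open, since whether the share varies between genes beyond counting error needs gene lengths, not used here for these genes. The spread of the ratios was 0.78 times that of other genes of like level, which leaves open that the isolate carries these genes.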

How the results depend on the processing

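The settings with lineage as a block, with libraries of 1 lineage averaged, without the 4 shallow libraries and with the MRS libraries of WCFS1 and LB16 alone were chosen after seeing the data. For 107 results on named genes, 3128 values under alternatives gave 2901 with the direction and call kept, 227 with the call lost and 0 reversed. The difference of correlations stayed between 0.086 and 0.123, and omnivore against vegan faecal extract gave 0 genes except without omnivore replicate 3.

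Counts of called genes moved by more than 1.5-fold as follows, and the cause was not tested. For the 9 strains (63), they were 96 at a mean of at least 10 RPKM, 186 centred, 197 with quantile normalization, 121 with genes above 0 in every strain, 178 over 36 libraries without a block, 315 with strain as a random block and 108 without the shallow libraries. Centred, wheat (271) gave 94, tomato (277) 141 and intestinal against plant media (1455) 777. With quantile normalization wheat gave 140, Drosophila (1535) 890 and intestinal against plant media 842, and wheat gave 469 with a pseudocount of 10. With lineage as a random block, wheat gave 605, tomato 454, bee (524) 850, omnivore (286) 641, vegan (398) 262, intestinal against plant media 573 and the F-test (2155) 855. With libraries of 1 lineage averaged, where fewer values were compared, wheat gave 28, tomato 54, bee 0 (limma, 289 at an unadjusted p under 0.05), vegan 62, pineapple 119, intestinal against plant media 727 and the F-test 946. Without the shallow libraries, wheat gave 524, tomato 463 and vegan 797. With the MRS libraries of WCFS1 and LB16 alone, where fewer libraries were compared, wheat gave 32, tomato 84, bee 134, omnivore 33, vegan 110, olive (529) 189 and pineapple (456) 123. With only the medium and MRS in the fit, wheat gave 121, omnivore 177, vegan 257 and pineapple 299. With an estimated correlation the called lists went from 7 to 0 in the 9 strains, 10 to 3 in bee, 14 to 0 in Drosophila, 9 to 0 in omnivore, 14 to 0 in vegan, 6 to 0 in tomato, 5 to 0 in olive, 6 to 0 in wheat, 8 to 0 in pineapple and 14 to 1 in intestinal against plant media. Wheat had 10 lists without the shallow libraries.

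Leaving out each library or strain in turn gave 22 to 147 genes in the 9 strains, 190 to 589 in bee, 1185 to 1675 in Drosophila, 104 to 337 in omnivore, 84 to 619 in vegan, 84 to 329 in tomato, 248 to 568 in olive, 46 to 363 in wheat, 145 to 539 in pineapple, 1947 to 2311 by the F-test, 1330 to 1580 in intestinal against plant media and 0 to 8 in omnivore against vegan. The lowest or highest counts that moved beyond 1.5-fold were 147 without strain DE12, 22 without TJ22, 46 without wheat replicate 2, 84 without tomato replicate 1, 84 without vegan replicate 2, 104 without omnivore replicate 3, 145 without pineapple replicate 3, 190 without bee replicate 2, 248 without olive replicate 3 and 619 without vegan replicate 1. Where 3 libraries remained 2, fewer samples were tested. Depth limits what a value of 0 means in Drosophila replicates 1 and 3, whose floors were 11.23 and 23.87 RPKM.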

Other observations

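The manganese test and the splits of lineage means were chosen after the results of the comparisons were seen.

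Other splits of the libraries were drawn 100 times for each comparison, the real one included. As many genes as the real split were called by 1 of 100 splits, the real one, in the 9 strains (63, highest other 3), bee (524, 287), Drosophila (1535, 641), omnivore (286, 82), vegan (398, 317), tomato (277, 153), olive (529, 162), pineapple (456, 257), the F-test (2155, 29) and intestinal against plant media (1455, 767), and by 2 of 100 in wheat (271, highest other 278). These splits exchange single libraries as if they were independent, and in the 9 strains swap the media within a strain. On that assumption chance is excluded at 0.05 as the sole source of these counts. With the libraries of 1 lineage and medium averaged and these means exchanged, 1 split of 78, the real one, called as many genes in Drosophila (1163, highest other 477) and 1 of 100 in the F-test (946, highest other 162), so chance is excluded there as well, if the lineages are counted rightly. As many as the real split were called by 8 of 78 in vegan (62, highest other 268), 7 of 78 in tomato (54, 279), 10 of 78 in wheat (28, 282) and 5 of 78 in pineapple (119, 271). For these 4 media chance is not excluded once isolates of a lineage count as 1. In bee, whose libraries are 1 lineage, the 12 splits are too few for a share under 0.05: the real one called 0 (limma, 289 at an unadjusted p under 0.05), 12 of 12 called as many, and the highest other called 464. Olive and omnivore hold 3 lineages each, so nothing was averaged there, and intestinal against plant media was not split by lineage means. Splits calling up to 767 genes point to structure among the libraries, which may be the medium. Of the 35 groupings of the 8 media into 4 and 4, 4 called at least as many genes as the intestinal and plant grouping, and the highest, bee, tomato, olive and wheat against the rest, called 1539. Chance choice of the media is therefore not excluded for this count. For omnivore against vegan faecal extract, the 10 splits are too few for a share under 0.05: the real one called 0, 10 of 10 called as many, and the highest other called 607, which points to structure among the 6 libraries.

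Among the plant media, the manganese uptake genes mtsA, mtsB, mtsC and mntH3 were low in pineapple juice, with a mean log2 value of 3.94 (highest library 4.49) against 9.34 (lowest 7.72) in tomato juice, olive extract and wheat flour hydrolysate. The difference was -5.40 (exact permutation p = 0.0045, two-sided, the smallest that 220 splits give). In MRS the mean was 3.27. A candidate explanation is that pineapple juice supplies more manganese than the other plant media. The medium's manganese was not measured, isolates differ between media and the genes were picked after their values were seen, so this stays a hypothesis.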
